A study of Homo sapiens with 6 samples.

How the data were processed

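Messenger RNA libraries were compared between 2 groups of MDA-MB-231 cells, a cell line from a triple-negative (estrogen receptor, progesterone receptor and HER2 negative) breast cancer. Per the labels, 3 libraries came from cells with a no-load control and 3 from cells overexpressing LARP6, an RNA-binding protein of the La-related family. Each library's group and replicate number were taken from its title. Total RNA was treated with DNase and made into libraries with a strand-keeping mRNA kit that were sequenced as paired reads of 150 bases, per the labels' protocols. The labels do not say that the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

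The authors deposited a table of read counts per gene and a table of FPKM values per gene, with a column for each library. HISAT2, DESeq2 and the build GRCh38 are named in the submitters' processing notes, without versions. The read counter, its strand setting and the annotation release are not given in the sources used here. The deposited counts were whole numbers with a different total in each library, and no gene was 0 in all 6 libraries. The deposited FPKM values are counts scaled by gene length and library size by the authors. The count table held 28675 genes, of which 16579 were protein coding and 7990 were lncRNA genes in its own annotation columns. The FPKM table lacked 336 of these genes, which had a median of 1 count over the 6 libraries. Of the gene identifiers, 28601 were matched to a table of gene names. GENCODE v29 on GRCh38, which held 97.0% of the identifiers, was used only for coordinates, transcript length, GC content and retained-intron transcripts.

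Counts were tested as deposited with edgeR 4.0.16 in R 4.3.3. Genes were kept by edgeR's expression filter, libraries were scaled by TMM, and LARP6 libraries were compared with control libraries by the robust quasi-likelihood test with no covariate. Calls were made at a Benjamini-Hochberg adjusted p below 0.05 over the 16226 genes tested. Adjusted p-values in the text are from this test unless another is named. Levels are CPM, the usual depth-normalised read counts, computed here from the counts with TMM-scaled library sizes. Depth was 29409101 to 33387050 counts per library, and the common dispersion gave a coefficient of variation between libraries of 3.23%. Exact binomial intervals at 95% cover counting error only, since reads without molecular identifiers are not independent molecules.

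Before the data were examined, 31 gene lists were written from textbook knowledge. Each list was tested with camera from limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, and list p-values were adjusted over the 31 lists. Members were also counted by the gene test and, separately, adjusted over the list alone. Another 4 lists (MHC class II genes, MHC class I genes, acute phase and complement genes, and transcripts with detained introns or poison exons) were written after the data had been seen, with p-values adjusted over these 4. The genes named in the text follow a rule set at the same time as the 31 lists. It takes LARP6, the collagen mRNAs COL1A1, COL1A2 and COL3A1, and protein-coding genes past the threshold with a mean of at least 5 CPM and no overlap between groups. Of these it takes the 6 largest and the 6 smallest p-values per direction. From each list it takes up to 4 members past the threshold with the smallest p, or the 2 with the smallest p where none passed. Other genes are said to have been chosen after their values were seen.

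The scripts were tested on simulated counts drawn from the means, dispersions and library sizes of these libraries, with 50 genes changed at each fold in each of 5 draws. The edgeR test recovered 51.2% of genes changed 1.2-fold, 66.0% at 1.3-fold and 80.4% at 2-fold. False calls averaged 7.46% of its calls, above the nominal 5%, against 3.26% for DESeq2. Camera called 0 of 200 simulated lists without change and called a list of 30 genes moved 1.2-fold. The simulated genes were drawn independently, so this does not test lists whose members vary together. The ribosomal list, for one, had an estimated correlation of 0.463 between members in the real libraries.

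The alternatives set beforehand were other scalings (RLE, upper-quartile and library size only), LARP6 left out of the counts, no low-count filter and a filter of CPM above 1 in 3 libraries. They also included DESeq2 1.42.0, limma-voom, limma on log2 of FPKM plus 1 or 0.1, a replicate block, an adjusted p below 0.01, camera with an estimated correlation, fry, and leaving out each library in turn. A fit with GC and length offsets, which takes out each library's smooth trend of log2 CPM on transcript GC content and length, was added after seeing the data. Alternative splicing and RNA binding sites were not analysed here, because both tables give 1 value per gene.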

Results

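Gene expression was measured by RNA sequencing in MDA-MB-231 breast cancer cells, with 3 control libraries and 3 libraries from cells overexpressing LARP6. The study was set up to ask which RNAs LARP6 binds and regulates, including their splicing, in triple-negative breast cancer. The deposited gene-level values address the part of this question that concerns RNA levels. Total counts were 30602721, 29723790 and 33387050 in control libraries 1, 2 and 3, and 29409101, 30197064 and 31648120 in LARP6 libraries 1, 2 and 3. Pairs of libraries within a group differed beyond sampling noise, with a chi-square of 2.11 to 3.82 per gene over 14722 genes. Each library was therefore counted as its own replicate, although this does not show that the libraries came from separate cultures. Pairs from different groups differed by 7.95 to 11.9 per gene. These values include LARP6 itself, which had 1200 counts in control library 2 and 67602 in LARP6 library 3. They were not computed without it, so they do not measure how far the groups differed in the other genes.

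LARP6 itself was raised about 49.3-fold in the overexpressing cells. LARP6 (ENSG00000166173.11) lies on chromosome 15 from 70829130 to 70854159 on the minus strand of GRCh38 in GENCODE v29. Its level was 42.7 ± 1.85 CPM (SD, n = 3) in control libraries and 2108 ± 104 CPM (SD, n = 3) in LARP6 libraries, a log2 fold change of 5.62 ± 0.04 (SE, edgeR adjusted p = 4.73e-94). Each library matched its label, with 44.2, 40.7 and 43.3 CPM in the controls and 1995, 2198 and 2131 CPM in the LARP6 libraries. In LARP6 library 1, the gene took 0.202% of counts (exact 95% interval 0.201% to 0.204%). The authors' FPKM values for LARP6 were 6.73 ± 0.306 (SD, n = 3) and 338 ± 17.3 (SD, n = 3). Gene-level counts do not separate transcripts of the introduced copy from those of the cell's own gene. Its neighbours on chromosome 15 did not pass the test, among them LRRC49, which overlaps it on the other strand, at a log2 fold change of 0.05 ± 0.21 (SE, edgeR adjusted p = 0.930).

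Several inflammatory genes were among the genes that fell most in the LARP6 libraries, and most changes were small. Of 30 tested members of the NF-kB list, 14 fell, 1 rose and 15 were not called (camera adjusted p = 2.83e-07, and adjusted p = 0.634 with an estimated correlation). LCN2, which encodes the iron-carrier-binding protein lipocalin 2, fell by 1.52 on the log2 scale (SE 0.07), a change of -65.2% from 37.5 ± 2.79 CPM (SD, n = 3) in the controls. The neutrophil-attracting chemokine gene CXCL1 fell by 1.07 (SE 0.07), and PDZK1IP1, a membrane protein gene, fell by 1.37 (SE 0.11). The complement gene C3 fell from 140 ± 9.05 to 86.7 ± 2.72 CPM (SD, n = 3 each), and the acute phase gene SAA1 from 244 ± 3.51 to 169 ± 10.9 CPM (SD, n = 3 each). Among the genes that rose, the largest changes by the naming rule after LARP6 were in EGR1, an early growth response transcription factor, at 0.76 ± 0.12 (log2, SE), and in NKTR, which encodes a cyclophilin-domain protein, at 0.50 ± 0.07. SLC7A11, the cystine transporter, rose by 0.47 ± 0.07, the minor-spliceosome factor gene CENATAC by 0.47 ± 0.07 and the RNA-binding protein gene CAPRIN2 by 0.46 ± 0.07.

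In all, 979 of 16226 tested genes passed the edgeR threshold, 395 higher and 584 lower. The median change was 1.16-fold among higher genes and 1.10-fold among lower genes, and 23 genes passed with at least a 2-fold change. Of these 23, the 4 with a mean of at least 5 CPM were LARP6, LCN2, CXCL1 and PDZK1IP1. The groups did not overlap in 22.3% of tested genes, against 10% by chance for 3 against 3 libraries. Scaled by library size only, the genes past threshold were 990, with 687 higher and 303 lower. With GC and length offsets, an alternative added after seeing the data, 604 genes passed and 417 of the 979 remained. The count was 459 without LARP6 library 1, 456 without LARP6 library 2 and 650 without control library 2. Of 93 named genes that passed, 39 lost their call without at least 1 of the libraries, among them VIM, CDH11, BUB1B, LOXL2, SERPINH1, P4HB, CYC1, KLF6, HNRNPH3, CTSB, CD14, TFF1, SPDEF, PGK1, MCM5, H2BC12, FBL, RRP9, NHP2, SLC3A2, COL4A2, COL8A1 and COL6A2.

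**Figure D1:**
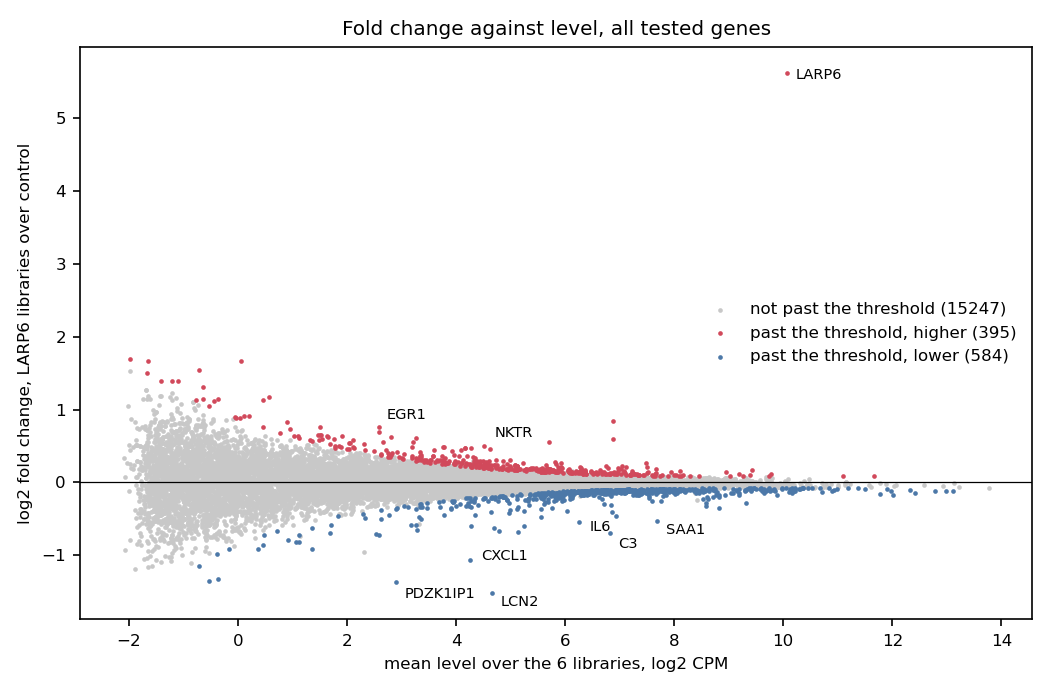
Each point is 1 of the 16226 tested genes, with its mean level over the 6 libraries in log2 CPM on the x axis and its log2 fold change, LARP6 libraries over control, on the y axis. Red points (395) passed the edgeR threshold as higher and blue points (584) as lower, and LARP6 stands alone at 5.62.

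In the list of NF-kB cytokines and inflammatory genes, 2 members were higher and 17 lower adjusted over the list alone, against 1 and 14 over all genes, with a camera adjusted p of 2.83e-07 and an adjusted p = 0.634 with an estimated correlation. With fry the list's adjusted p was 0.0471. The cytokine gene IL6 fell from 90.7 ± 5.56 to 61.8 ± 3.10 CPM (SD, n = 3 each), a log2 change of -0.55 ± 0.04 (SE, edgeR adjusted p = 1.63e-22). The chemokine gene CXCL8 fell by 0.66 (SE 0.06), and ZC3H12A, an RNase gene that restrains cytokine mRNAs, by 0.69 (SE 0.05). The member that rose was BIRC3, an inhibitor of apoptosis, at 0.20 ± 0.04, and its call was lost with GC and length offsets. The leukocyte list had 6 tested members, of which CD14 fell by 0.35 (SE 0.09) and 5 were not called (1 lower adjusted over the list alone, camera adjusted p = 0.427).

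A pair of related lists was written after their genes had been seen to fall, so their tests are not independent evidence. Of 12 tested MHC class II genes, which serve antigen presentation, 10 fell and 0 rose (12 lower adjusted over the list alone), with a camera adjusted p of 7.18e-15 and an adjusted p = 0.0225 with an estimated correlation. CD74, the invariant chain gene, changed by -0.35 ± 0.03 (log2, SE) and HLA-DRA by -0.40 ± 0.03. Of 11 acute phase and complement genes, 9 fell and 0 rose (1 higher and 10 lower adjusted over the list alone), with a camera adjusted p of 5.77e-13 and an adjusted p = 0.0208 with an estimated correlation. Among them C1S changed by -0.72 ± 0.12 and SERPINA1 by -0.37 ± 0.05. SAA1 and its near-identical copy SAA2, and HLA-DRB1 and HLA-DRB5, can share reads, so the size of each one's change is uncertain.

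**Figure D2:**
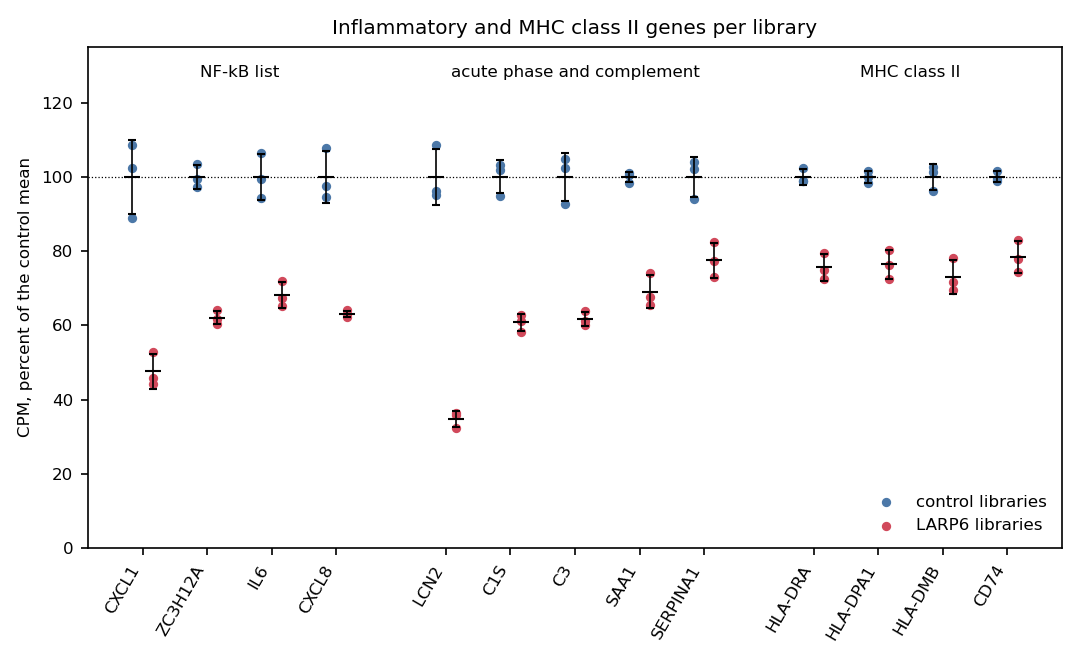
CPM of each gene in each library as a percent of the control mean, with control libraries in blue and LARP6 libraries in red. Horizontal marks are means and bars SDs (n = 3), and for each gene shown the LARP6 libraries lay below the control libraries, with LCN2 changed by -65.2% in the fit.

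Collagen mRNAs were of interest because LARP6 is known to bind a stem-loop in type I and type III collagen mRNAs. COL1A1 was at 3.75 ± 0.508 CPM in controls and 4.11 ± 0.622 CPM in LARP6 libraries (SD, n = 3 each; log2 fold change 0.14 ± 0.15, SE, edgeR adjusted p = 0.675), a difference within the spread. COL1A2 was below 1 CPM in each group mean (0.648 and 0.709 CPM, log2 fold change 0.13 ± 0.33, SE, edgeR adjusted p = 0.883). COL3A1 had 1 count over the control libraries and 2 over the LARP6 libraries and was not tested. Of 19 collagen chains, COL4A2, COL8A1 and COL6A2 fell by 0.14, 0.12 and 0.13 on the log2 scale and 16 were not called (3 lower adjusted over the list alone, camera adjusted p = 0.440). Of 21 collagen processing enzymes and chaperones, 4 fell and 0 rose (6 lower adjusted over the list alone), with a camera adjusted p of 0.00535, an adjusted p = 0.634 with an estimated correlation and 0.0609 with fry. They were the glycosyltransferase gene COLGALT1 (-0.14 ± 0.03), the crosslinking enzyme gene LOXL2 (-0.12 ± 0.03), the collagen chaperone gene SERPINH1 (-0.09 ± 0.03) and P4HB (-0.08 ± 0.03). The called processing genes numbered 2 without control library 1 or control library 2 and 1 without LARP6 library 2, and the called chains 1 without control library 1 or LARP6 library 1 and 0 without LARP6 library 2. With library size only, the chains were 1 higher and 1 lower and the processing genes 0 higher and 2 lower. With GC and length offsets, the chains were 1 higher and 2 lower and the processing genes 0 higher and 3 lower.

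Lists of ribosomal, mitochondrial and lipid genes passed with camera as lower, with small changes. With fry, which tests change against none, the adjusted p was 0.125 for the ribosomal, 0.130 for the mitochondrially encoded, 0.126 for the respiratory chain and 0.0471 for the lipid list. Of 75 cytosolic ribosomal protein genes, 22 fell and 0 rose (41 lower adjusted over the list alone) and 53 were not called, with a median change of -3.98%, a camera adjusted p of 1.55e-07 and an adjusted p = 0.634 with an estimated correlation. The 22 became 5 without LARP6 library 1, 7 without control library 2, 8 without control library 3, 9 without LARP6 library 2 and 10 when scaled by library size only, and 27 with DESeq2, 30 with limma-voom and 40 with the replicate block. Of 13 mitochondrially encoded mRNAs, 8 fell (11 adjusted over the list alone; camera adjusted p = 0.000127, and adjusted p = 0.634 with an estimated correlation), among them MT-ND3 at -0.14 ± 0.03. The 8 became 3 with GC and length offsets, 3 with limma-voom, 5 with DESeq2 and 11 with the replicate block. All mitochondrial genes together took 7.63% ± 0.259 of counts in controls and 7.28% ± 0.114 in LARP6 libraries (SD, n = 3 each). Of 33 nuclear-encoded respiratory chain genes 1 fell, CYC1 at -0.10 ± 0.03, and 32 were not called (4 lower adjusted over the list alone; camera adjusted p = 0.00423, and adjusted p = 0.634 with an estimated correlation). The camera adjusted p was 0.0562 without control library 3 and 0.0611 without LARP6 library 1, and the members lower were 5 without LARP6 library 3, 6 with the replicate block, 3 with GC and length offsets, and 0 with library size only or without control library 3, LARP6 library 1 or LARP6 library 2. Of 31 cholesterol and fatty acid synthesis genes, 12 fell and 0 rose (15 lower adjusted over the list alone; camera adjusted p = 4.75e-05, and adjusted p = 0.634 with an estimated correlation), including DHCR7 at -0.21 ± 0.03 and the fatty acid synthase gene FASN at -0.14 ± 0.03. The 12 became 5 without LARP6 library 2 and 8 without control library 2 or LARP6 library 1. Ribosomal protein genes have many processed pseudogenes, so their values are uncertain where reads could be split.

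Splicing regulators and immediate early genes were the 2 lists past the camera threshold as higher, with 40 of 47 and 17 of 24 members not called and fry adjusted p of 0.0665 and 0.00169. Of 47 SR proteins, hnRNPs and other splicing regulators, 7 rose and 0 fell (10 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00909, and adjusted p = 0.634 with an estimated correlation). SRSF10 rose by 0.19 ± 0.03 (log2, SE), HNRNPH1 by 0.16 ± 0.03, SRSF11 by 0.17 ± 0.04 and HNRNPH3 by 0.12 ± 0.03. With GC and length offsets the list no longer passed and its direction turned, with 1 member higher and 3 lower (camera adjusted p = 0.943, with a range over the alternatives of 1.44e-06 to 0.943), while 13 rose and 0 fell with library size only. Of 24 immediate early genes, 6 rose and 1 fell (7 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0424, and adjusted p = 0.634 with an estimated correlation). KLF4 rose by 0.25 ± 0.04 and KLF6 by 0.13 ± 0.03, while JUND changed by -0.16 ± 0.03. The immediate early list had an adjusted p of 0.0674 without control library 2, 0.0982 without control library 3, 0.0611 without LARP6 library 1 and 0.147 without LARP6 library 3. Its call was also lost with the replicate block (0.0567), DESeq2 (0.116) and a filter of CPM above 1 in 3 libraries (0.0615), and 3 of its members rose without LARP6 library 1 or LARP6 library 2. The splicing regulators had 0.0502 without control library 3 and 0.0611 without LARP6 library 1, and 4 members rose without control library 2, LARP6 library 1 or LARP6 library 2. Epithelial junction and keratin genes passed with camera as lower, with 2 of 19 called, ELF3 at -0.32 ± 0.07 and KRT80 at -0.13 ± 0.03 (2 lower adjusted over the list alone; camera adjusted p = 0.00930, and adjusted p = 0.634 with an estimated correlation and 0.0522 with fry), and the list's call was lost with GC and length offsets (0.278, with a range over the alternatives of 0.00613 to 0.634).

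Interferon-stimulated genes went both ways. Of 41 tested members, 6 rose and 6 fell (10 higher and 8 lower adjusted over the list alone; camera adjusted p = 0.219), and 3 rose without control library 3, LARP6 library 1 or LARP6 library 2. Among them the RNA sensor genes IFIT2 and IFIT1 rose by 0.27 ± 0.03 (log2, SE) and 0.20 ± 0.03, while IFITM3 changed by -0.18 ± 0.03 and IFI27 by -0.25 ± 0.03. With GC and length offsets IFIT2, IFIT1, IFITM3 and IFI27 kept their calls. The higher genes IFI44, DDX58 and HERC5 and the lower genes LGALS3BP and BST2 lost theirs, and were picked for that loss after their values were seen.

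**Figure D3:**
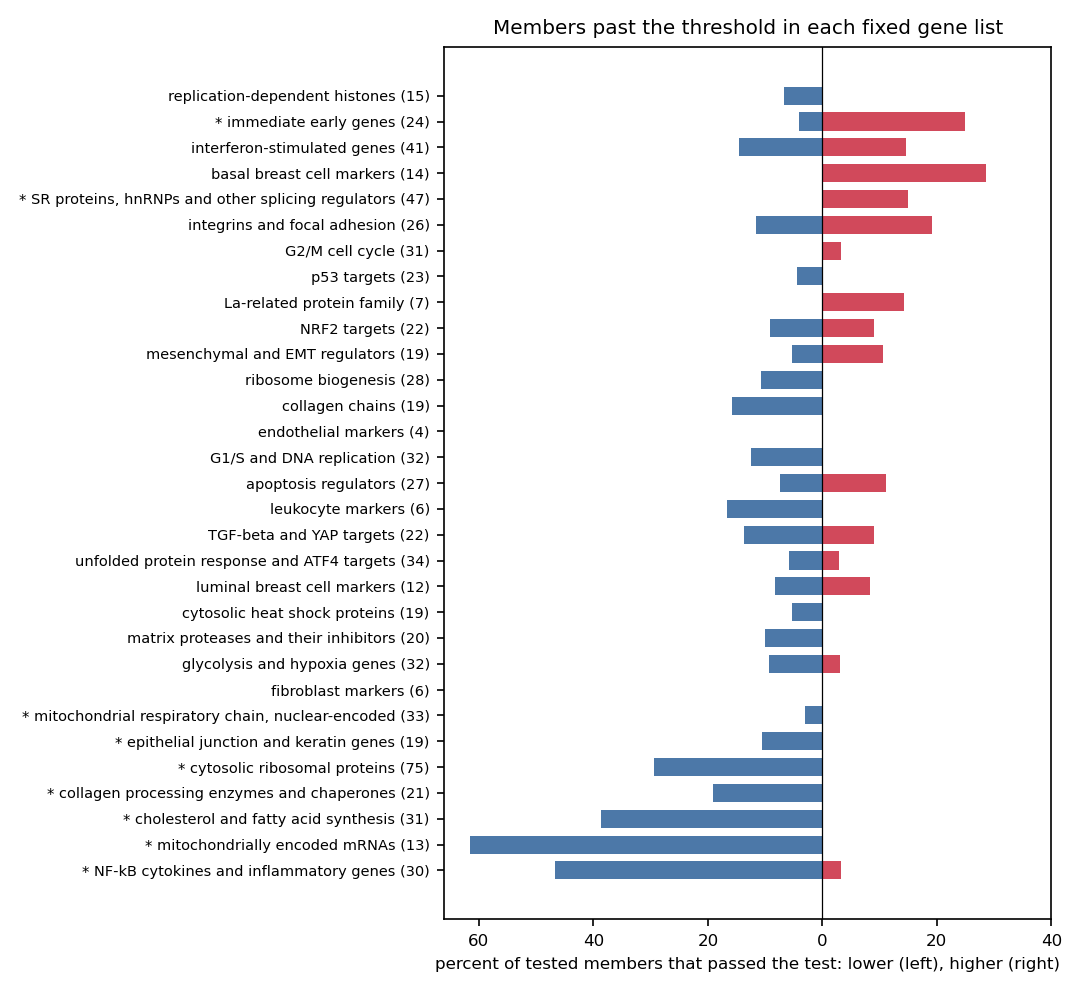
Percent of tested members past the edgeR threshold in each of the 31 lists, lower to the left in blue and higher to the right in red, with the number of tested members in brackets and lists in order of median log2 fold change. Asterisks mark the 9 lists past the camera threshold with the preset correlation, while 0 passed with an estimated correlation (1 at an unadjusted p under 0.05). With fry 5 lists passed, among them the G1/S and La-related lists, which have no asterisk.

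The remaining lists did not pass with camera. Under the alternatives the adjusted p ran from 0.0483 (DESeq2) to 0.744 for basal breast markers, from 0.0446 (without control library 1) to 0.634 for the unfolded protein response, and, lowest on unfiltered FPKM, from 0.0171 to 0.634 for integrins and from 0.0395 to 0.782 for G2/M genes. With fry the G1/S list (0.0473) and the La-related list (0.00116) passed. The La-related list holds LARP6 itself, so its pass does not speak for the other members. With LARP6 left out of the counts, 0 of the 6 remaining members were called (camera adjusted p = 0.761). The 22 lists that did not pass had 29 higher members, LARP6 among them, and 39 lower members. Members were counted per list, so a gene on several lists, such as ITGB4, was counted in each. The higher and lower members became 12 and 19 without LARP6 library 1, 14 and 17 without LARP6 library 2, and 29 and 44 without LARP6 library 3. They were 19 and 29 without control library 1, 21 and 26 without control library 2, 18 and 25 without control library 3, and 46 and 22 with library size only. Of 26 integrin and focal adhesion genes, 5 rose and 3 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.219), with ITGB4 at 0.15 ± 0.03. That split was 9 higher and 0 lower with library size only, 1 and 0 without control library 3 or LARP6 library 1, and 2 and 0 without control library 1 or LARP6 library 2. Of 14 basal breast markers 4 rose, ITGB4 among them (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.416). With each library left out in turn, the other basal markers that rose lost their calls, CAV1 and CAV2 in 5 fits each and ITGA6 in 3. Of 12 luminal breast markers, TFF1 rose by 0.40 ± 0.11 and SPDEF changed by -0.14 ± 0.04 (1 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.440). Of 19 mesenchymal and EMT regulators, VIM and CDH11 rose by 0.09 and 0.12 and LOXL2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.911). Of 20 matrix proteases and inhibitors, MMP15 changed by -0.32 ± 0.07 and CTSB by -0.09 ± 0.03 (3 higher and 4 lower adjusted over the list alone; camera adjusted p = 0.361). Of 31 G2/M genes, BUB1B rose by 0.15 ± 0.05 (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.446), and of 32 G1/S and DNA replication genes 4 fell, including CDT1 and MCM5 (4 lower adjusted over the list alone; camera adjusted p = 0.185). Among these G1/S genes, with each library left out in turn, E2F1 lost its call in 4 fits and MCM2 and MCM5 in 2 each. Of 27 apoptosis regulators, 3 rose, including PMAIP1 at 0.21 ± 0.03, and 2 fell, including BID at -0.23 ± 0.05 (3 and 2 adjusted over the list alone; camera adjusted p = 0.957). Of 23 p53 targets GDF15 changed by -0.36 ± 0.05 (1 lower adjusted over the list alone; camera adjusted p = 0.911).

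Of 22 TGF-beta and YAP targets, 2 rose and 3 fell, with TGM2 at -0.28 ± 0.03 (3 and 3 adjusted over the list alone; camera adjusted p = 0.515). Of 34 unfolded protein response and ATF4 targets, SLC7A11 rose and DDIT4 and SLC3A2 fell (1 higher and 7 lower adjusted over the list alone; camera adjusted p = 0.0758). Of 19 cytosolic heat shock proteins HSPB1 changed by -0.14 ± 0.03 (1 lower adjusted over the list alone; camera adjusted p = 0.361). Of 32 glycolysis and hypoxia genes, 1 rose and 3 fell, including PGK1 at -0.10 ± 0.03 (1 and 6 adjusted over the list alone; camera adjusted p = 0.179). Of 22 NRF2 targets, SLC7A11 and NQO1 rose and FTH1 was among those that fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.957). Of 28 ribosome biogenesis genes, FBL, RRP9 and NHP2 fell (4 lower adjusted over the list alone; camera adjusted p = 0.546). Of 15 replication-dependent histone genes H2BC12 fell (1 lower adjusted over the list alone; camera adjusted p = 0.446), and of 7 La-related genes LARP6 alone was called (1 higher adjusted over the list alone; camera adjusted p = 0.361). None of the 4 endothelial or 6 fibroblast markers tested was called by edgeR, over all genes or adjusted over the list alone (0 of each, also at an unadjusted p under 0.05 and with limma-voom; camera adjusted p = 0.957 and 0.760). DESeq2 gave an adjusted p for 2 of the endothelial markers and 0 of the fibroblast markers, so it says little on them. The smallest p-values there belonged to ESAM, KDR, PDGFRB and FBLN1, with edgeR adjusted p of 0.407, 0.811, 0.364 and 0.544. The sign of the camera test differed from that of the median in the p53, mesenchymal, apoptosis, NRF2 and endothelial lists, and the mean differed from the median in the p53, mesenchymal and luminal lists.

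Higher and lower genes also differed in length and base composition. Protein-coding genes that rose had a median transcript length of 5206 bases and a GC content of 42.5%, those that fell 2329 bases and 57.8%, and all tested ones 3640.5 bases and 48.4%. Across 13184 protein-coding genes, which are not independent replicates, the log2 fold change had a Spearman correlation of 0.271 with length and -0.385 with GC content. In the quintile of genes with the lowest GC content, the median deviation from the control mean was 0.02, 0.02 and -0.04 (log2) in the control libraries and 0.07, 0.07 and 0.03 in the LARP6 libraries. Of 93 named genes that passed the threshold, 33 lost their call with GC and length offsets, among them HNRNPH1, RPL35, SERPINH1 and P4HB.

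**Figure D4:**
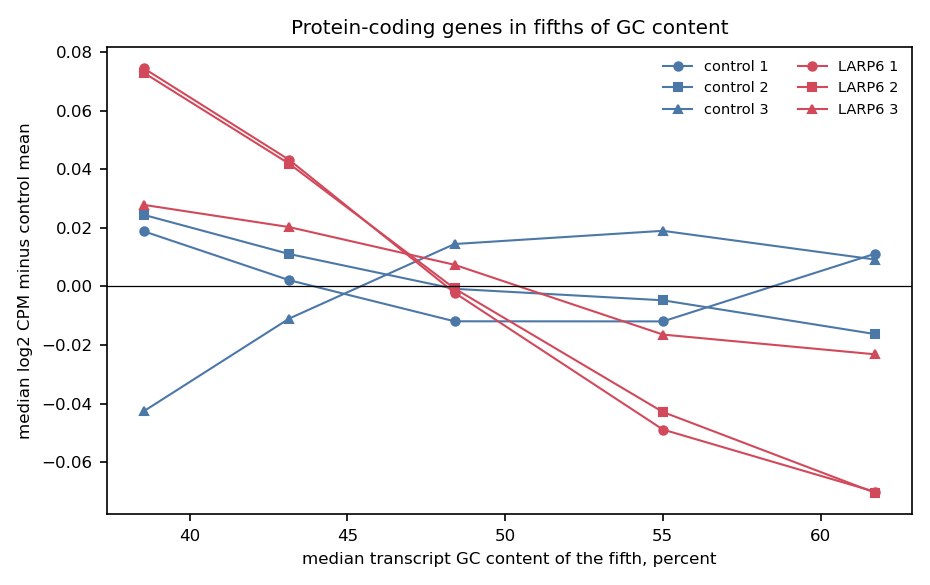
Median log2 CPM minus the control mean (y axis) for protein-coding genes in quintiles of transcript GC content (x axis, median percent of each quintile), with a line for each library, control in blue and LARP6 in red. In the lowest-GC quintile the control libraries ran from -0.04 to 0.02 and the LARP6 libraries from 0.03 to 0.07.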

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

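The rule behind the value in this part, and the choice of the related genes, came after the data were seen. IFNL2, which encodes an interferon of the lambda family, fell below the expression filter and was outside the gene test. It had 0 counts in each control library and 9, 5 and 7 counts in LARP6 libraries 1, 2 and 3, a total of 21. Among 12449 genes below the filter, it was the 1 gene with more than 3 counts in each LARP6 library and 0 in the controls, and 0 genes met the reverse. With at least 2 counts in each library of a group, 10 genes met the rule for LARP6 and 6 the reverse, so the looser rule separated the directions less. IFNL3, a near-identical copy that can share reads with IFNL2, had 2 counts over the controls and 21 over the LARP6 libraries, a depth-scaled ratio with an exact 95% counting interval of 2.64 to 94.9. IFNL1 had 12 and 35 counts and did not pass in the gene test (log2 fold change 1.53 ± 0.53, SE, edgeR adjusted p = 0.0675). Counts this low carry counting error in addition to the spread between libraries, and no cause was tested.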

How the results depend on the processing

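The fit with GC and length offsets was added after seeing the data; the other alternatives were set beforehand. Against 979 genes past threshold (395 higher, 584 lower, 23 with a 2-fold change), library size only gave 687 higher and 303 lower, and a filter of CPM above 1 in 3 libraries left 7 with a 2-fold change, since it removes low genes. DESeq2 called 574 genes (164 higher, 3 with a 2-fold change), with an adjusted p for 8105 genes; 251 of the 979 were not called and 176 had no adjusted p. On log2 of FPKM plus 1, limma called 90 genes (37 higher, 53 lower, 3 with a 2-fold change). With 0.1 added it called 92 (38, 54 and 5), and with no filter 3 (1, 2 and 2). GC and length offsets gave 604 genes (203 higher), and 562 of the 979 calls were lost. An adjusted p below 0.01 left 443. The cause was not tested for the DESeq2, FPKM and offset counts.

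Leaving out each library in turn gave 456 to 1040 genes past threshold, 175 to 398 higher, 281 to 642 lower and 15 to 27 with a 2-fold change. The count moved over 1.5 times without LARP6 library 1 (459), LARP6 library 2 (456) and control library 2 (650), with fewer libraries in each fit. LARP6 stayed between 5.59 and 5.66. Of the uncalled genes, COL1A2 ran from -0.0816 (without LARP6 library 1) to 0.24, KDR from -0.22 to 0.0281 (without LARP6 library 1) and FBLN1 from -0.28 to 0.00517 (without control library 3), so their directions turned.

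Of 31 lists, 9 passed with camera, 7 with GC and length offsets, 6 to 10 with a library left out, 0 with an estimated correlation and 5 with fry, which does not compare a list with other genes. The 5 with fry include the La-related list, which holds LARP6. With an estimated correlation the 9 lists shared the adjusted p of 0.634. Lists that had not passed, among them the G1/S and integrin lists, had the same value, so it does not tell the lists apart. The estimated correlation was -0.0282 for immediate early genes and 0.00395 for epithelial genes, below the preset 0.01. A correlation above the preset therefore does not account for the loss in these lists. The list of SR proteins, hnRNPs and other splicing regulators turned direction with GC and length offsets (adjusted p = 0.943), and the cause was not tested. The NF-kB list ranged from 3.64e-09 to 2.95e-05 with a library left out.

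The replicate block gave 1345 genes past threshold, 974 of them among the 979. Same-numbered libraries had correlations of 0.0985, 0.0444 and 0.234. Control library 2 correlated best with LARP6 library 1 (0.0687), while control library 3 had -0.149 and -0.106 with LARP6 libraries 1 and 2. A batch shared by libraries of the same number was thus neither shown nor excluded, and the labels do not name one. At this depth the simulated test recovered 51.2% of genes changed 1.2-fold, so changes of that size or smaller can be missed. The simulation changed fewer genes than the 979 called here and picked them at random. Its 51.2% is therefore not the recovery in these data.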

Other observations

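The nuclear RNAs, the added lists, the GC and length offsets, the tests of library scaling and of GC and length bias on the NF-kB list and the tests of the GC trend in this part were chosen after the results were seen, and the bounds of these tests were set with their values known. The nuclear-retained RNAs MALAT1, NEAT1 and KCNQ1OT1 rose in the LARP6 libraries, and these 3 genes do not stand for noncoding RNAs as a class. MALAT1 rose from 84.6 ± 7.82 to 152 ± 11.9 CPM (SD, n = 3 each), a log2 fold change of 0.85 ± 0.09 (SE, edgeR adjusted p = 0.0147), and NEAT1, the scaffold of paraspeckles, from 94.0 ± 9.11 to 142 ± 10.2 CPM (0.59 ± 0.09, edgeR adjusted p = 0.0401). KCNQ1OT1 rose by 1.18 ± 0.25 (edgeR adjusted p = 0.000659), a call lost without LARP6 library 1 (0.0876). NEAT1 lost its call without control library 1 (0.118), LARP6 library 1 (0.0664) or LARP6 library 2 (0.150). With GC and length offsets MALAT1 stood at 0.77 (edgeR adjusted p = 0.0303) and NEAT1 lost its call at 0.50 (edgeR adjusted p = 0.123). Of 20 transcripts with detained introns or poison exons, 9 rose and 0 fell (13 higher adjusted over the list alone; camera adjusted p = 5.17e-08, and adjusted p = 0.0208 with an estimated correlation). With GC and length offsets 5 rose and the list's median was 0.08 against 0.15 without (camera adjusted p = 2.19e-06), and 5 rose with DESeq2 and without control library 2, LARP6 library 1 or LARP6 library 2. The 9 included NKTR, TIA1 (0.47 ± 0.07), DMTF1 (0.44 ± 0.07) and OGT (0.21 ± 0.04). Of 12 MHC class I genes, 5 fell, with HLA-B at -0.18 ± 0.03 (7 lower adjusted over the list alone; camera adjusted p = 0.000409, and adjusted p = 0.182 with an estimated correlation).

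For the fall in inflammatory genes, a scaling factor moves all genes of a library alike, whereas the 30 tested NF-kB list members, against the other genes of the same library, had a median log2 difference between the groups of -0.193 (pooled SD 0.0685), with each LARP6 library below each control, which argues against library scaling. LARP6 library 3 stood apart at -0.0881, against -0.253 and -0.234 in the other LARP6 libraries and -0.0248 in control library 1, and the other scalings set beforehand as a test moved all genes too little to decide. With GC and length offsets the median log2 change of the 30 members was -0.165 against -0.192 without (camera adjusted p = 1.18e-06, while without offsets the adjusted p = 0.634 with an estimated correlation), which argues against that trend as the whole cause. A loss of leukocytes as the source of the fall in CD74, by 110 CPM, is argued against by 7 leukocyte genes that summed to 0.878 CPM in the controls, although CD14, not among the 7, fell from 12.4 to 9.71 CPM and the leukocyte list with it from 23.0 to 20.2 CPM. A lower inflammatory state in cells with more LARP6 is a hypothesis that stays open and untested, as does a difference between cultures or clones, which the labels do not describe.

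Noncoding genes were 47 of 395 higher genes (11.9%) and 24 of 584 lower genes (4.11%), an odds ratio of 3.15 (Fisher's exact test, two-sided, p = 7.20e-06), with 18.4% among tested genes, and it was 6.37 with GC and length offsets, which argues against that trend as the cause. Genes are not independent replicates, so the Fisher p and the permutation p-values that follow do not measure the spread between libraries. Within expression deciles the median log2 fold change of lncRNA genes differed from that of protein-coding genes by -0.0174 (permutation p = 0.0943). With GC and length offsets the sign of this difference turned, at 0.0161 (permutation p = 0.237). Both lay inside the bound set beforehand for low expression, so the low level of noncoding genes may account for part of the pattern. Protein-coding genes with an annotated retained-intron transcript lay 0.0018 above those without (permutation p = 0.507), which decided nothing on unspliced RNA. Genomic DNA stays open too: the share of counts in genes under 0.5 CPM, as the lowest LARP6 library minus the highest control library, was -0.000240 percentage points. This met the bound set beforehand against genomic DNA, but by less than the SD between libraries of 0.00320, a margin applied after the value was seen.

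Long, AT-rich genes were higher and short, GC-rich genes lower. In the lowest-GC quintile the range of the 3 control libraries was 1.15 times the difference between the groups (0.07 against 0.06, log2). That met the bound set for a GC bias that varies between libraries. The range rested on control library 3 (-0.04, against 0.02 in control libraries 1 and 2). LARP6 library 3 was also the lowest of its group (0.03, against 0.07 in LARP6 libraries 1 and 2). Each LARP6 library lay above each control library. An offset shared by the libraries numbered 3 would widen the range without making the group difference. The range therefore does not decide whether such a bias underlies the trend. With total counts as a covariate the difference was 0.0418 ± 0.00745 (SE), 71.9% of its size, between the bounds set for and against depth, which stays open. An effect of LARP6 on such genes stays open and was not tested.

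The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The other splits put control and LARP6 libraries together in each group. Differences between control and LARP6 libraries then add to the spread within groups. Counts from the other splits are therefore not those of data without a group difference. The real split was 1 of 10 with as many genes past the threshold (979, highest other 0), higher genes (395, highest other 0), lower genes (584, highest other 0), genes with a 2-fold change (23, highest other 0) and gene lists (9, highest other 4).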
